A study of Mus musculus with 11 samples.

How the data were processed

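The study profiled gene expression in cells of the adult mouse subventricular zone (C57BL/6) on NimbleGen arrays: 7 arrays of sorted cells and 4 of monolayer cultures. Per the labels, the sorted populations were separated by a published flow cytometry protocol, and the cultures were moved to medium without growth factors for 1, 2 or 4 days. RNA was extracted with trizol, amplified with a whole transcriptome kit and labelled with Cy3, per the labels.

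The deposited per-array values are in intensity units on a linear scale. Per the file headers, images were read with DEVA 1.2 on a design named after the mm9 genome, and each value is the mean over the probes of a target. The submitters' processing notes name RMA, but the deposited values were whole numbers with a different median on each array, the highest 1.80 times the lowest. They were thus neither log-transformed nor normalized between arrays. Whether background had been corrected cannot be told from this. The deposited series table held the same intensity values in 100% of 485881 cells compared. Of 44170 targets, 44155 had 3 probes and 15 had fewer. The probe values were already averaged, so the median polish planned for unnormalized probe intensities could not be run on them. The deposited coefficient of variation within targets (other unit) was used only for the 5000 random control probes.

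Symbols were updated through the Entrez identifiers of the files with a RefSeq table, used for names only; 39057 targets matched and 5650 symbols changed. Intensities were background-corrected with normexp (offset 50), quantile normalized over the 11 arrays and put on the log2 scale with limma 3.58.1 in R 4.3.3. For each of 24172 symbols the target with the highest mean was kept. A gene counted as above background on an array when its intensity exceeded the random control mean plus 2 standard deviations. Folds against a group not above background are lower bounds, written "at least", and no fold is given where neither group was above background. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

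The sorted arrays were grouped by their labels and fitted together with limma (lmFit and eBayes), with 3 residual degrees of freedom and 3.04 prior degrees of freedom. The NB group has 1 array, which was assumed to vary like the groups of 2. The comparisons were a moderated F-test over the 4 populations and moderated tests of NSC minus astrocytes, TA minus NSC and NB minus TA, two-sided and adjusted by Benjamini-Hochberg over 24172 genes at 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 18 lists within each contrast. Alternatives were fry and camera with an estimated correlation, which leaves it the 3 residual degrees of freedom. Camera compares a list with all other genes, and fry compares it with no change. In total 54 list tests were made. The lists were cell cycle, activated progenitor, neuroblast, astrocyte, Notch pathway, BMP and Id, receptor kinase feedback, chromatin regulators, ribosome biogenesis, glycolysis, fatty acid oxidation, oligodendrocyte lineage, mature neuron, ependymal, microglia, endothelial and mural, immediate early and stress, and noncoding RNA. Of 382 entries 367 were matched to a target; Plk1, Cenpe, Ube2c, Gsx2, Sp9, Plxna4, Thbs4, Notch3, Jag2, Spry2, Nefm, Nefh, Egr1, Klf2 and Malat1 were not analysed here. Lists, comparisons and tests were fixed before the data were examined.

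Culture arrays have no replicates and were described without a test. A gene was counted when it differed at least 2-fold (log2 1) on day 4 with days 1 and 2 on the same side. List medians were placed among 10000 random lists matched on expression in 50 bins. Culture differences were correlated with sorted differences across genes.

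The named genes were, by a rule fixed before the data were examined, the 8 largest rises and 8 largest falls per comparison among called genes whose arrays did not overlap between groups, leaving out provisional symbols. They were ranked on fitted differences, so the order among lower bounds is not known. The genes used for the sort, and up to 4 members of each list with the largest change, were added by the same rule. Some genes that the rule selects are not used here. The 12 largest rises and falls of day 2 were added after the data were examined.

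With simulated changes of log2 1 and 2 in 100 genes each, the procedure called 80% and 98% for NSC minus astrocytes, 66% and 99% for TA minus NSC and 34% and 96% for NB minus TA; the F-test called 97.5% at log2 2. It called 16, 11, 5 and 9 unchanged genes in these tests and 0 of 17 unchanged lists in each contrast. The simulated genes were drawn independently with the fitted spread and no array effect. False calls from correlated genes or from an unusual array were therefore not assessed. The culture rule counted 200 of 200 genes changed by log2 2, an outcome fixed by construction because the simulated cultures had no noise.

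Alternatives tried were the values as deposited, centring on array medians, no background correction, the mean of all targets of a gene, leaving out the dimmest 30% of genes, trend and robust moderation, a fold floor, leaving out each replicate, a replicate block, fits of the compared groups alone, and other rules for the culture. Alternatives added after the data were examined left out the NB, day 1 and day 4 arrays or genes below background, compared NB rises with receptor genes, or used day 2 alone.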

Results

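Gene expression was measured in adult mouse cells of the subventricular zone, the stem cell niche along the lateral ventricles, with single-colour NimbleGen arrays holding 44170 gene targets on each of 11 arrays. Sorted cells gave 7 arrays: 2 of activated neural stem cells (NSC), 2 of transit amplifying cells (TA), 1 of neuroblasts (NB) and 2 of niche astrocytes. Monolayer cultures gave 4 arrays: 1 of proliferating cells and 1 each from days 1, 2 and 4 after growth factors were withdrawn. The labels do not say whether replicate arrays came from separate animals, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision, the culture had no replicates, and the lone NB array was assumed to vary like the groups of 2.

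Random control probes, whose signal serves as background, had mean intensities from 516 to 716 per array. The 95th percentile of the gene targets was 15.1 and 16.2 times that control mean on the NSC arrays, 19 and 29.2 times on the TA arrays, 15.8 and 15.5 times on the astrocyte arrays and 6.36 times on the NB array. In culture it was 15.2 times in proliferating cells, 9.74 on day 1, 17.0 on day 2 and 12.1 on day 4. Targets above the background limit, the control mean plus 2 standard deviations, made up 48.7% of all on the proliferating array and 80.9% on day 4, the lowest and highest shares of the 11 arrays. Replicate arrays correlated across genes at 0.983 in NSC, 0.991 in TA and 0.987 in astrocytes, where genes are not independent replicates. On the leading axis of a multidimensional scaling of the 11 arrays, the NB array (2.54), day 1 (1.39) and day 4 (2.62) lay apart from the other 8, which ran from -1.63 to -0.35. Olfactory and vomeronasal receptor genes, 920 genes chosen after this was seen because few are known to be active outside sensory neurons, had a median intensity of 1.40 times the control mean on the NB array, 1.38 on day 1 and 2.29 on day 4, against 0.931 to 1.18 on the other 8.

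**Figure D1:**
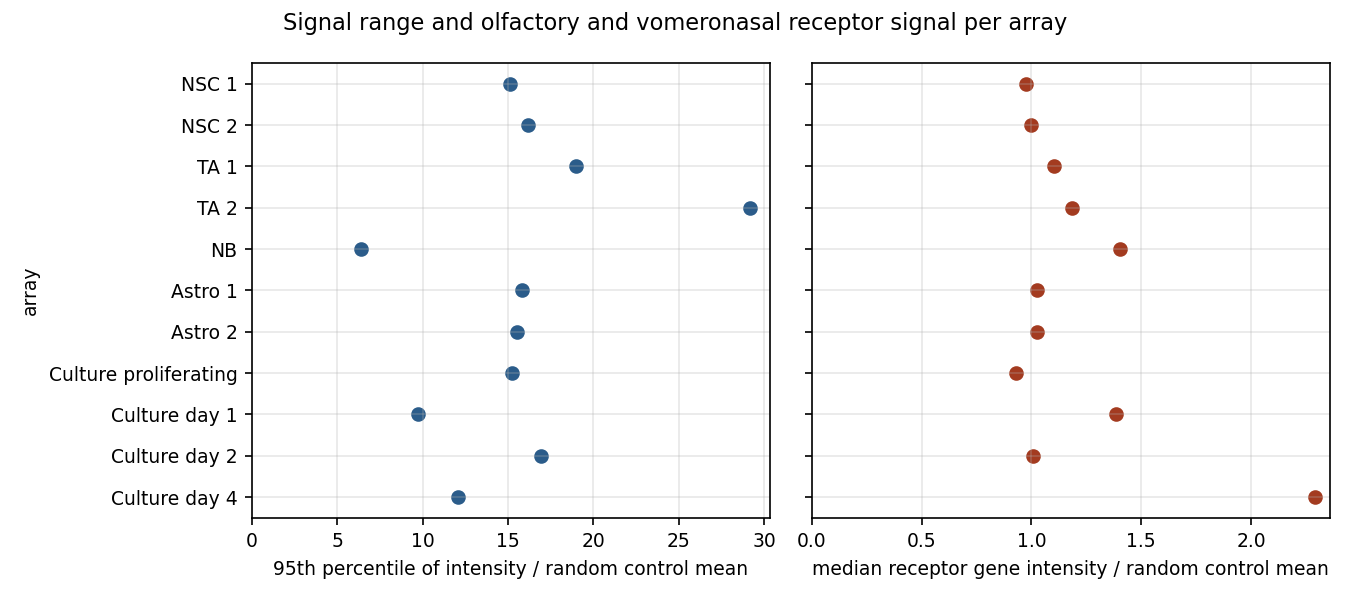
Each row is an array, with the 95th percentile of target intensity over the random control mean on the left and the median intensity of the receptor genes over the same mean on the right. Receptor genes sat at 1.38 to 2.29 times the control mean on the NB, day 1 and day 4 arrays and at 0.931 to 1.18 times on the other 8.

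Most genes differed somewhere among the sorted populations. Of 24172 genes tested, 19434 (80.4%) passed the moderated F-test of limma over the 4 groups at an adjusted p of 0.05. That count was 15016 over the 3 other groups in a fit without the NB, day 1 and day 4 arrays, an alternative chosen after the data were examined.

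Activated stem cells differed from niche astrocytes, the other population that the cited sort takes as Gfap reporter-positive, in cell cycle, progenitor and glial genes. All 35 measured cell cycle genes were higher in NSC, among them Cdc20, an activator of the anaphase-promoting complex, at a log2 level of 13.78 ± 0.17 (SD, n = 2) against 8.72 ± 0.10 (SD, n = 2). Of the activated progenitor list 16 of 17 genes were higher too, such as Mycn, a transcription factor gene of cell growth, by at least 17.1-fold. Of the astrocyte list 19 of 29 genes were lower in NSC and 1 higher, the water channel gene Aqp4 being 2.68-fold and S100b 2.91-fold lower. With an estimated correlation each of these 3 list calls was lost (adjusted p = 0.0665). In the limma test of NSC minus astrocytes, 10839 of 24172 genes passed at an adjusted p of 0.05, 5239 higher in NSC and 5600 lower. At least 2-fold differences numbered 4542, and 1530 of the called genes were above background in neither group. The direction depended on scaling: as deposited, without normalization, 2008 genes were higher and 14673 lower, and with each array centred on its median 59.4% were higher.

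Among the largest fitted rises in NSC over astrocytes were cell division and replication genes and a haemoglobin gene. Cdk6, a kinase of the G1 phase (chromosome 5, 3522764 to 3525260, mm9), rose by at least 23.3-fold (log2 5.34 ± 0.20, SE; adjusted p = 4.68e-05). Pole, which encodes a subunit of DNA polymerase epsilon, rose by at least 27.7-fold, and Spc24, a kinetochore gene (chromosome 9, 21560541 to 21564730), by at least 22.6-fold. Cdc20 rose by a fitted 33.5-fold (log2 5.06 ± 0.13, SE), with 1 of 2 astrocyte arrays above background. Shcbp1, Cenpm and Cdca7l rose by at least 10.8-fold, 12.8-fold and 17.0-fold. Hbb-b2, a beta-globin gene of red blood cells, rose by at least 14.9-fold. Among the largest fitted falls were S100a3 by at least 8.27-fold (log2 -4.16 ± 0.31, SE), Acer3 by at least 8.94-fold and Vamp5 by at least 6.86-fold, followed by Gdap2 (at least 3.81-fold), Zmat1 (3.12), Wdr27 (3.05) and Vmn2r-ps41 (1.61). Ipcef1 was called lower as well (log2 -4.06 ± 1.29, SE; adjusted p = 0.0447), but its astrocyte arrays had an SD of 3.12 (n = 2) and the call was lost in several alternatives. Of the genes that the sort uses, Egfr was 2.38-fold and Cd24a 8.47-fold higher in NSC. Differences in these genes may follow from the gates, and whether the gates account for that of Cd24a was not tested. Gfap differed by -0.06 on the log2 scale (adjusted p = 0.782), or by -0.49 as deposited (adjusted p = 0.0168).

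Of the 18 gene lists fixed before the data were examined, 11 shifted between NSC and astrocytes by the camera test with its preset correlation, and none of these calls held with an estimated correlation. Counts of members adjusted over the list alone equalled those over all genes unless given. In the cell cycle list 35 of 35 members rose (median log2 2.92; camera adjusted p = 7.56e-21; adjusted p = 0.0665 with an estimated correlation), among them Ccnb1 by 23.7-fold, Prc1 by 21.4-fold and Cdt1, a replication licensing factor, by at least 13.9-fold. In the activated progenitor list 16 of 17 members rose and 0 fell (median 2.16; camera adjusted p = 4.01e-09; adjusted p = 0.0665 with an estimated correlation), including Insm1 by at least 13.5-fold. In the neuroblast list 19 of 26 members rose and 1 fell (median 1.54; camera adjusted p = 2.89e-07; adjusted p = 0.0665 with an estimated correlation), with Gad2, a GABA synthesis enzyme, up by 7.65-fold and Igfbpl1 by at least 5.46-fold. In the ribosome biogenesis list 15 of 20 members rose and 1 fell (median 0.86; camera adjusted p = 0.000105; adjusted p = 0.0890 with an estimated correlation), including the small nucleolar RNP genes Gar1 by 3.42-fold and Nhp2 by 3.04-fold. In the astrocyte list 19 of 29 members fell and 1 rose, or 20 and 1 adjusted over the list alone (median -0.59; camera adjusted p = 3.3e-05; adjusted p = 0.0665 with an estimated correlation), with Vcam1 down by 2.57-fold. In the fatty acid oxidation list 10 of 18 members fell and 0 rose (median -0.48; camera adjusted p = 0.0028; adjusted p = 0.144 with an estimated correlation), Acadvl, the very long chain acyl-CoA dehydrogenase, by 3.18-fold. In the oligodendrocyte lineage list 9 of 18 members fell and 2 rose (median -0.41; camera adjusted p = 0.0300; adjusted p = 0.151 with an estimated correlation), and among the members down most were the precursor genes Pdgfra by 5.17-fold and Gpr17 by 3.76-fold.

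Several marker lists of other cell types were also higher in NSC than in astrocytes. Other cells in the NSC sort were not tested as a source. In the mature neuron list 13 of 18 members rose and 1 fell (median 1.42; camera adjusted p = 6.53e-05; adjusted p = 0.181 with an estimated correlation), including the GABA transporter gene Slc32a1 by 5.95-fold. In the microglia list 12 of 18 members rose and 0 fell (median 1.16; camera adjusted p = 9.23e-05; adjusted p = 0.0751 with an estimated correlation), including Ctss by 6.86-fold. In the endothelial and mural list 12 of 19 members rose and 2 fell, or 12 and 3 adjusted over the list alone (median 1.15; camera adjusted p = 0.00343; adjusted p = 0.0975 with an estimated correlation), including Pecam1 by 9.04-fold. In the immediate early and stress list 15 of 21 members rose and 2 fell, or 16 and 2 adjusted over the list alone (median 0.97; camera adjusted p = 8.89e-05; adjusted p = 0.0890 with an estimated correlation), with Fos up by 6.59-fold and Gadd45b down by 4.75-fold. No shift passed for Notch (camera adjusted p = 0.852), BMP and Id (0.0727), receptor kinase feedback (0.323), chromatin regulators (0.102), glycolysis (0.349), ependymal (0.952) or noncoding RNA (0.0727) genes. Of these, the ependymal list had 7 higher and 6 lower members of 18 (7 and 7 adjusted over the list alone), with a median of 0.14 and a mean of -0.02. Within the Notch list the ligand gene Dll3 rose by at least 4.53-fold and Dll1 by a fitted 10.7-fold with 1 of 2 astrocyte arrays above background, while 10 of 17 members fell. Its median (-0.55) and the test were negative and its fitted mean (0.34) positive. With members below background at their bound the median was 2.74 for cell cycle, 1.39 for neuroblast, 1.18 for mature neuron, 1.08 for endothelial and mural, and 0.82 for immediate early and stress genes. As deposited the calls for fatty acid oxidation (adjusted p = 0.062) and oligodendrocyte lineage (0.123) genes were lost.

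**Figure D2:**
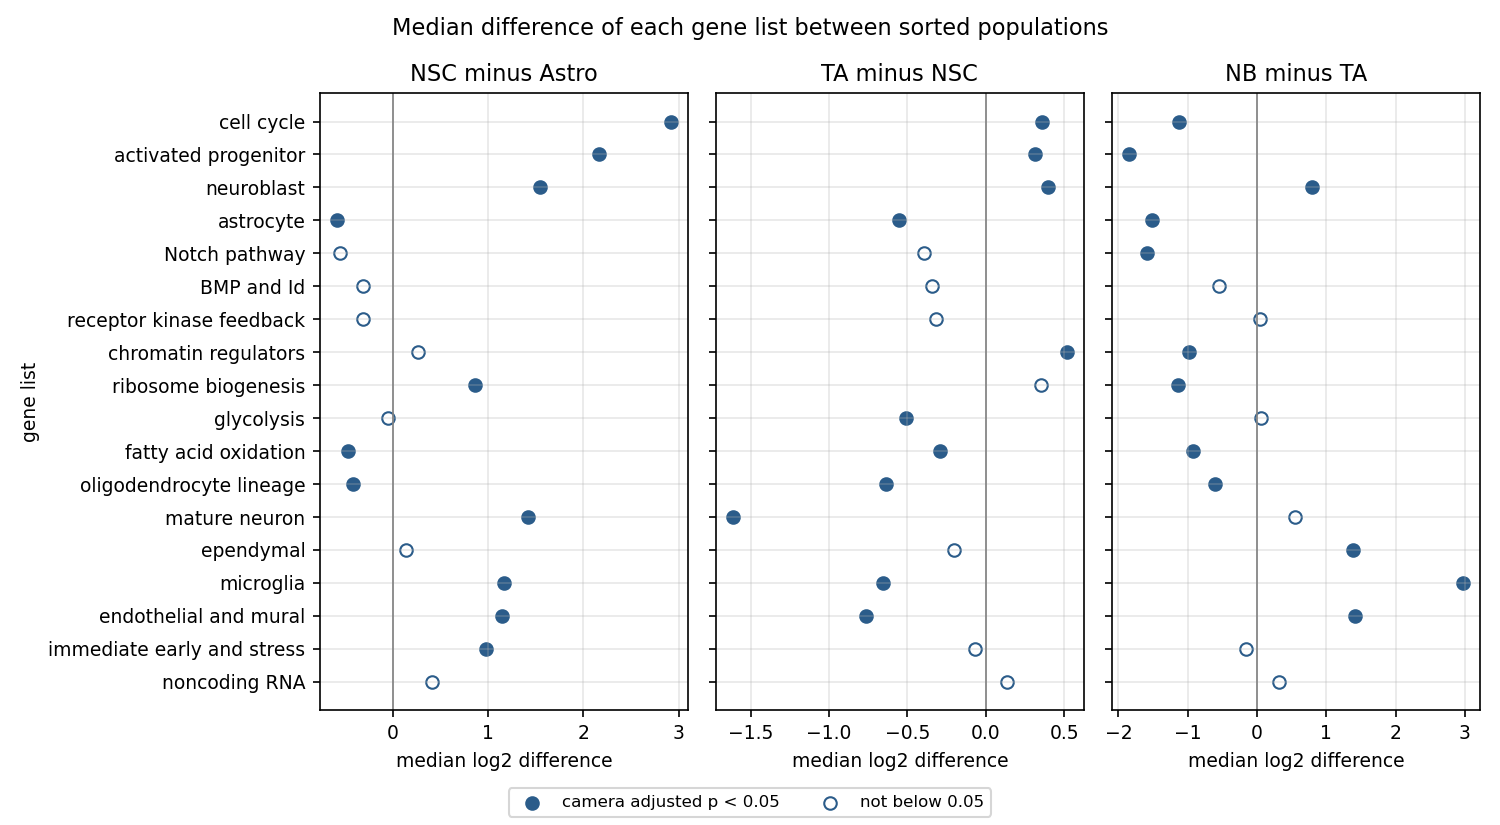
Median log2 difference of each of the 18 gene lists in NSC minus astrocytes, TA minus NSC and NB minus TA, with filled points for a camera adjusted p under 0.05 at the preset correlation, none of which held with an estimated correlation. Cell cycle genes had medians of 2.92, 0.36 and -1.13, and the neuroblast list of NB minus TA turned its sign in the values as deposited.

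From activated stem cells to transit amplifying cells, 15 of 35 cell cycle genes and 15 of 23 chromatin regulator genes rose, and globin genes fell, as did most genes of the astrocyte, oligodendrocyte lineage and mature neuron lists. Globin genes had mean log2 levels of 13.81 and 13.92 on the NSC arrays against 8.26 and 8.33 on the TA arrays. Whether globin genes and markers of other cell types came from stem cells or from other cells in the NSC sort was not tested. The proliferation marker Mki67 rose by 4.36-fold and Dcx, which encodes the microtubule protein doublecortin of migrating neuroblasts, by 3.60-fold. The largest measured fall was of Hbb-b1, a beta-globin gene, by 68.5-fold, from a log2 level of 14.94 ± 0.05 (SD, n = 2) in NSC to 8.85 ± 0.14 (SD, n = 2) in TA. The synaptic vesicle gene Syt1 fell by 13.2-fold. In the limma test of TA minus NSC 9915 of 24172 genes passed at an adjusted p of 0.05, 4781 higher in TA and 5134 lower. Of the called genes 1789 were above background in neither group, and 3366 differed at least 2-fold. The count fell to 6085 without TA replicate 1 and to 5523 without TA replicate 2. With each array centred on its median alone, which moved the median of all genes to -0.34, 27.5% of the called genes were higher in TA, against 48.2% here. As deposited 15811 of 16667 were higher.

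Among the largest fitted rises in TA over NSC was Rad50, a DNA repair gene (chromosome 11, 53463020 to 53482015), by at least 6.43-fold (fitted log2 4.65 ± 0.20, SE; adjusted p = 0.000165). The histone chaperone-binding gene Hirip3 rose by at least 7.13-fold, the deubiquitinase gene Usp28 by at least 5.70-fold, Cip2a by at least 4.78-fold and Sos1, an activator of Ras, by at least 4.22-fold. Tmem74, Hmgn5 and Klhl10 rose by at least 3.70-fold, 2.25-fold and 1.94-fold. The alpha-globin genes Hba-a1 and Hba-a2 fell by at least 50.2-fold and 41.9-fold, and Hbb-b2 by at least 18.6-fold. These globin copies are near-identical in sequence, and whether the probes tell them apart was not tested. Lamb1, a laminin chain gene (chromosome 12, 31950180 to 31970611), fell by at least 14.5-fold (log2 -4.67 ± 0.16, SE; adjusted p = 0.000139). Nxph1, a neurexin ligand gene, fell by 21.3-fold, Dnm1, a dynamin gene of synaptic vesicle recycling, by a fitted 25.4-fold with 1 of 2 TA arrays above background, and Zfp389 by at least 6.12-fold. Of the sort genes Gfap was 2.31-fold lower in TA, Egfr differed by -0.04 on the log2 scale (adjusted p = 0.868) and Cd24a by 0.38 (adjusted p = 0.0561). As deposited none of these held: Gfap stood at -0.18 (adjusted p = 0.262), Egfr at 0.73 and Cd24a at 1.13 (adjusted p = 0.000981).

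Of the 18 lists 11 shifted between NSC and TA by camera, and again none held with an estimated correlation. In the chromatin regulator list 15 of 23 members rose and 0 fell, or 18 and 1 adjusted over the list alone (median 0.52; camera adjusted p = 8.69e-05; adjusted p = 0.111 with an estimated correlation), among them Suz12 of the Polycomb repressive complex by 2.32-fold and Bmi1 by 1.97-fold. In the cell cycle list 15 of 35 members rose and 3 fell (median 0.36; camera adjusted p = 0.000937; adjusted p = 0.135 with an estimated correlation), Cenpf by 3.42-fold. In the activated progenitor list 6 of 17 members rose and 0 fell (median 0.31; camera adjusted p = 0.00364; adjusted p = 0.147 with an estimated correlation), with the homeobox gene Dlx1 up by 2.39-fold and Ccnd1 by 2.19-fold. In the neuroblast list 13 of 26 members rose and 4 fell, or 15 and 4 adjusted over the list alone (median 0.39; camera adjusted p = 0.00381; adjusted p = 0.111 with an estimated correlation), with Dcx up by 3.60-fold and Gad1 down by 8.80-fold. In the astrocyte list 19 of 29 members fell and 0 rose, or 22 and 0 adjusted over the list alone (median -0.56; camera adjusted p = 2.69e-06; adjusted p = 0.111 with an estimated correlation), including Agt by 3.88-fold and Slc4a4 by 2.86-fold. In the glycolysis list 9 of 17 members fell and 0 rose (median -0.51; camera adjusted p = 0.00364; adjusted p = 0.111 with an estimated correlation), including Pfkp by 2.79-fold and the glucose transporter gene Slc2a1 by 1.97-fold. In the fatty acid oxidation list 6 of 18 members fell and 0 rose, or 5 and 0 adjusted over the list alone (median -0.29; camera adjusted p = 0.0194; adjusted p = 0.183 with an estimated correlation), Cpt2 by 2.86-fold.

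Marker lists of 4 other cell types fell from NSC to TA. In the mature neuron list 15 of 18 members fell and 1 rose (median -1.62, or -1.32 with members below background at their bound; camera adjusted p = 1.49e-06; adjusted p = 0.135 with an estimated correlation), with the NMDA receptor gene Grin1 down by at least 7.53-fold. In the oligodendrocyte lineage list 11 of 18 members fell and 0 rose (median -0.64; camera adjusted p = 0.000432; adjusted p = 0.111 with an estimated correlation), including the myelin gene Mog by 2.92-fold. In the microglia list 12 of 18 members fell and 1 rose, or 13 and 1 adjusted over the list alone (median -0.66; camera adjusted p = 0.000947; adjusted p = 0.111 with an estimated correlation), with Cd53 down by 3.12-fold and Cd68 up by 2.12-fold. In the endothelial and mural list 12 of 19 members fell and 2 rose, or 13 and 2 adjusted over the list alone (median -0.76; camera adjusted p = 0.00047; adjusted p = 0.111 with an estimated correlation), with Acta2, a smooth muscle actin gene, down by at least 5.02-fold. No shift passed for Notch (camera adjusted p = 0.147), BMP and Id (0.0824), receptor kinase feedback (0.304), ribosome biogenesis (0.0663), ependymal (0.0522), immediate early and stress (0.424) or noncoding RNA (0.464) genes. Among the noncoding RNAs 6 of 22 rose and 6 fell, and Dlx6os1, a transcript at the Dlx5 and Dlx6 locus (chromosome 6, 6770545 to 6811648), rose by at least 6.33-fold (log2 2.93 ± 0.11, SE). As deposited the calls for neuroblast (adjusted p = 0.14), glycolysis (0.088) and fatty acid oxidation (0.335) genes were lost. Over the 3 contrasts together, 6 list calls were gained in that setting.

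On the neuroblast array, most listed progenitor and cell cycle genes were lower than in transit amplifying cells, and genes of microglia and globin genes were higher. Egfr, the receptor for epidermal growth factor and a sort gene (chromosome 11, 16652245 to 16787661), was at least 18.6-fold lower, and Fabp7, a progenitor fatty acid-binding protein gene, 19.5-fold lower. Of the neuronal genes Stmn2, a regulator of microtubules, was 6.48-fold higher and Gad1 5.36-fold higher. Trem2, a myeloid receptor gene, was 19.5-fold higher. In the limma test of NB minus TA 15486 of 24172 genes passed at an adjusted p of 0.05, 8610 higher on the NB array and 6876 lower, 10850 of them at least 2-fold, and the median of all genes was 0.16. The p-values assume that this lone array varies like the groups of 2. Its receptor signal calls that into doubt, so the calls describe this array and not neuroblasts in general. As deposited, without normalization, 39.3% of the called genes were higher against 55.6% here. Receptor genes, whose signal was raised on this array, had a median difference of 1.02, with 530 of 920 called higher and 21 lower, and only 305 of the 8610 rises exceeded their 97.5th percentile of 3.73.

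Among the largest fitted rises on the NB array were globin genes, Hba-a1 by at least 92.3-fold, Hba-a2 by at least 94.5-fold, Hbb-b2 by at least 91.0-fold and Hbb-b1 by 82.0-fold (log2 6.36 ± 0.15, SE; adjusted p = 2.85e-05). Prss58 rose by at least 39.9-fold, Cfap57, a gene of motile cilia, by at least 28.1-fold, the connexin gene Gjb5 by at least 22.5-fold and Alox5ap, a leukotriene synthesis gene of leukocytes, by at least 15.9-fold. Egfr fell by at least 18.6-fold (adjusted p = 2.85e-05). Ncapg, a condensin gene, fell by at least 12.4-fold, the cyclin gene Ccna2 by at least 8.64-fold, Lix1 by at least 9.35-fold, Amy1 by at least 10.7-fold, Bola1 by at least 10.1-fold and Zfp449 by at least 3.41-fold. The sort gene Cd24a was 1.93-fold higher (log2 0.95 ± 0.16, SE), but at -0.48 as deposited and 0.18 (adjusted p = 0.389) with each array centred on its median, and Gfap was below background on the NB array.

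**Figure D3:**
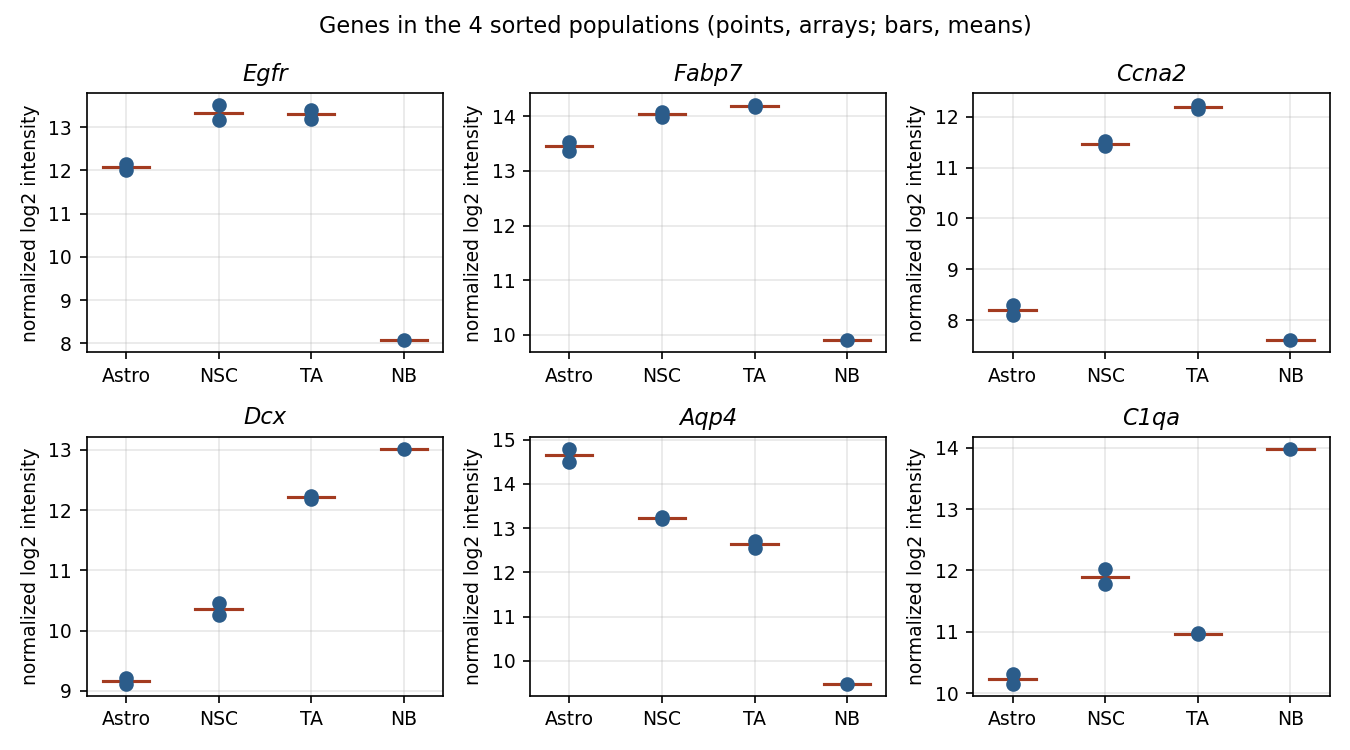
Normalized log2 intensity of 6 genes in the 4 sorted populations, where points are arrays and bars are group means. Egfr lay at 13.33 in NSC, 13.29 in TA and 8.07 on the NB array, and C1qa, a microglia gene, lay highest on the NB array (13.98).

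Of the 18 lists 12 shifted between TA and the NB array by camera, and none held with an estimated correlation. In the cell cycle list 28 of 35 members fell and 1 rose, or 29 and 1 adjusted over the list alone (median -1.13; camera adjusted p = 3.33e-07; adjusted p = 0.0804 with an estimated correlation), Top2a by 6.23-fold. In the activated progenitor list 11 of 17 members fell and 0 rose (median -1.85; camera adjusted p = 3.46e-05; adjusted p = 0.0900 with an estimated correlation), with Olig2 down by 10.2-fold. In the Notch list 12 of 17 members fell and 1 rose (median -1.59, or -0.77 with members below background at their bound; camera adjusted p = 0.000133; adjusted p = 0.0804 with an estimated correlation), with Jag1 down by at least 6.82-fold, the nuclear effector gene Rbpj by at least 6.71-fold and Dll1 by 5.78-fold. In the chromatin regulator list 16 of 23 members fell and 0 rose (median -0.98; camera adjusted p = 1.74e-05; adjusted p = 0.0804 with an estimated correlation), Suz12 by at least 7.96-fold. In the ribosome biogenesis list 14 of 20 members fell and 2 rose (median -1.14; camera adjusted p = 0.000419; adjusted p = 0.0913 with an estimated correlation), with Nop58 down by 8.53-fold. In the fatty acid oxidation list 14 of 18 members fell and 2 rose, or 15 and 2 adjusted over the list alone (median -0.93; camera adjusted p = 0.000286; adjusted p = 0.0913 with an estimated correlation), Hadh by 6.57-fold. In the astrocyte list 24 of 29 members fell and 1 rose (median -1.52; camera adjusted p = 3.8e-07; adjusted p = 0.0798 with an estimated correlation), with the gap junction gene Gja1 down by 12.9-fold and Aqp4 by 8.91-fold. In the oligodendrocyte lineage list 10 of 18 members fell and 3 rose, or 10 and 4 adjusted over the list alone (median -0.60, or -0.38 with members at their bound; camera adjusted p = 0.0445; adjusted p = 0.150 with an estimated correlation), with Ugt8a, a gene of myelin lipid synthesis, down by 3.94-fold.

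In the neuroblast list 17 of 26 members rose and 1 fell (median 0.79; camera adjusted p = 0.0227; adjusted p = 0.123 with an estimated correlation), including the transcription factor gene Sp8 by 4.26-fold. Relative to the median of all genes this list stood at 0.62, but at -0.30 in the values as deposited, so its direction depended on the scaling. In the microglia list 18 of 18 members rose (median 2.97; camera adjusted p = 3.18e-07; adjusted p = 0.0798 with an estimated correlation), including Tyrobp, a signalling adaptor of myeloid cells, by 12.3-fold, Tmem119 by 12.6-fold and Aif1 by at least 13.1-fold. In the endothelial and mural list 14 of 19 members rose and 0 fell, or 15 and 0 adjusted over the list alone (median 1.41; camera adjusted p = 0.000894; adjusted p = 0.0900 with an estimated correlation), including Eng by 3.85-fold. In the ependymal list 11 of 18 members rose and 3 fell (median 1.38, or 1.02 with members at their bound; camera adjusted p = 0.0258; adjusted p = 0.150 with an estimated correlation), including Tmem212 by at least 17.7-fold and the cilia gene Ccdc40 by 11.2-fold. As deposited, the endothelial and mural call was lost (adjusted p = 0.236). With the mean of all targets per gene the neuroblast (0.181), oligodendrocyte lineage (0.131) and ependymal (0.0526) calls were lost. The rises of these marker lists stand beside the receptor genes' median of 1.02, whose 97.5th percentile was exceeded by 2 of 18 microglia genes, 1 ependymal gene and 0 neuroblast genes. In the endothelial and mural list Acta2 (log2 4.46) exceeded it, and the next largest called change was that of Ly6c1 (2.06). No shift passed for BMP and Id (camera adjusted p = 0.152), receptor kinase feedback (0.637), glycolysis (0.928), mature neuron (0.0672), immediate early and stress (0.637) or noncoding RNA (0.859) genes. The camera direction was down for 4 of these lists whose median, mean or both were positive: receptor kinase feedback (median 0.04, mean -0.23), glycolysis (0.05 and 0.05), immediate early and stress (-0.16 and 0.09) and noncoding RNA (0.31 and 0.00).

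In culture, growth factor withdrawal was followed by higher neuroblast and ependymal genes and lower cell cycle, growth factor feedback and glycolysis genes, with 1 array per time point and no test. Dcx (chromosome X, 140305152 to 140367662) was at least 12.5-fold higher on day 2 and at least 19.3-fold higher on day 4 than in proliferating cells. Dlx6os1 was at least 14.0-fold and at least 12.1-fold higher on these days. Vegfa, the vascular growth factor gene (chromosome 17, 46162144 to 46168699), was 44.9-fold lower on day 4. On day 4, 6317 of 24172 genes lay at least 2-fold from the proliferating culture with days 1 and 2 on the same side, 2844 higher and 3473 lower. The count was 3305 without background correction, 53.1% of them higher, and 3252 as deposited, 63.7% of them higher. Receptor genes stood at 0.99 above the proliferating culture on day 1, at -0.03 on day 2 and at 1.89 on day 4, and the 8 largest fitted rises on day 4 were 7 vomeronasal receptor genes, among them Vmn1r127 (at least 22.6-fold), and Obox4-ps18. With each array centred on its median 21.9% of the counted genes were higher, against 45.0% here, and the median of all genes was -0.54.

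Among the largest falls on day 4, the centromere protein gene Cenpf was 30.9-fold lower, Cenpi at least 18.1-fold and the collagen gene Col18a1 at least 17.2-fold. Gpd1, a glycerol phosphate dehydrogenase, was 23.3-fold lower, and Ifitm10, Rassf3 and Aldh1a3, a retinoic acid synthesis gene, were at least 16.3-fold, 19.2-fold and 16.5-fold lower. Since the receptor genes were not raised on day 2, the 12 largest rises and 12 largest falls of that day were added after the data were examined. Cmtm5 (chromosome 14, 55555319 to 55558110) was at least 26.4-fold higher. Myt1, a zinc finger gene of neuronal differentiation, was at least 14.1-fold higher, Dlx6 at least 16.5-fold, Dlx1 15.1-fold, Slc32a1 at least 4.70-fold and Lmo3 at least 8.28-fold. Dynlrb2, a dynein light chain gene, was at least 17.5-fold higher, followed by Elobl (5.03) and Nat8f5 (4.94), also as lower bounds. The lactate transporter gene Slc16a3 was at least 16.3-fold lower on day 2, Ccnd1, the cyclin of growth factor response, 14.8-fold and Adm, which encodes adrenomedullin, 11.8-fold. Rab3b was at least 11.6-fold lower, Trib2 at least 6.61-fold and Rapgef4 at least 5.60-fold, and lower bounds from 2.68 to 8.01 applied to Vmn1r207, Fancb, Fam71f2, Prss35, Gcnt4 and Adam12.

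The gene lists in culture were placed among 10000 random lists of the same size and expression. Neuroblast genes had medians of 0.32, 1.54 and 1.38 on days 1, 2 and 4, at percentiles 98.2, 100 and 100, with 16 of 26 members at least 2-fold higher and 0 lower on day 2. Ependymal genes had medians of 0.84, 1.09 and 1.49, or 0.33, 0.74 and 1.17 with members below background at their bound. Their percentiles were 99.7, 100 and 100. On days 1 and 4 the medians of the neuroblast and ependymal lists lay below those of the receptor genes, 0.99 and 1.89. On day 2 both lay above the receptor median of -0.03. Cell cycle genes had medians of -0.99, -0.39 and -2.92 at percentiles 0, 0.06 and 0, and 32 of 35 were at least 2-fold lower on day 4. Receptor kinase feedback genes had medians of -1.63, -1.21 and -1.99, each below all 10000 random lists (-1.31, -1.21 and -1.99 at their bound), and Dusp6 was 4.86-fold and Spry4 7.56-fold lower on day 2. Glycolysis genes had medians of -0.56, -0.33 and -0.61 at percentiles 0, 0 and 0.03, Hk2 being 7.17-fold lower on day 2. Notch genes had medians of -0.36, -0.48 and -0.82 with percentiles of 7.84, 0.84 and 0.86, or medians of -0.03, 0.00 and -0.43 at their bound, and Hes1 was at least 2.88-fold lower on day 2. Activated progenitor genes had medians of 0.37, -0.48 and -0.47, where Olig2 was 7.34-fold lower and Dlx2 5.15-fold higher on day 2. BMP and Id genes had medians of -0.20, -0.52 and -0.26, or 0.00 on each day at their bound, with Id1 4.34-fold lower on day 2. Astrocyte genes had medians of 0.30, 0.20 and 0.10, or 0.26, 0.02 and 0.00 at their bound. Their percentiles were 99.9, 98.3 and 94.2.

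For the remaining lists the medians on days 1, 2 and 4 were -0.19, -0.25 and -0.73 for ribosome biogenesis, -0.16, 0.31 and 0.01 for chromatin regulators, and -0.14, 0.01 and -0.45 for fatty acid oxidation. They were -0.26, -0.17 and 0.19 for oligodendrocyte lineage genes, with Olig1 15.5-fold lower on day 4, and 0.04, 0.07 and 0.61 for mature neuron genes. Microglia genes had medians of 0.00, 0.22 and 0.82, endothelial and mural genes of -0.16, -0.60 and -0.23, and 12 or 13 members of each of these lists allowed no fold on a given day because neither array was above background or the fold was not defined. Immediate early and stress genes had medians of -0.39, -0.06 and -0.74, and noncoding RNAs of 0.12, 0.27 and 0.53 at percentiles 73.9, 98.2 and 98.6. With members below background at their bound the medians were 0.00 on all 3 days for the mature neuron, microglia, endothelial and mural, oligodendrocyte lineage, and immediate early and stress lists. The fitted medians of these lists set no direction. At their bound the medians were 0.00, 0.12 and 0.00 for chromatin regulators and 0.00, 0.035 and 0.24 for noncoding RNAs. Under other scalings the sign relative to all genes turned on day 1 for activated progenitor, neuroblast, astrocyte, oligodendrocyte lineage, endothelial and mural, and noncoding RNA genes, and on day 4 for astrocyte, chromatin regulator, and endothelial and mural genes.

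**Figure D4:**
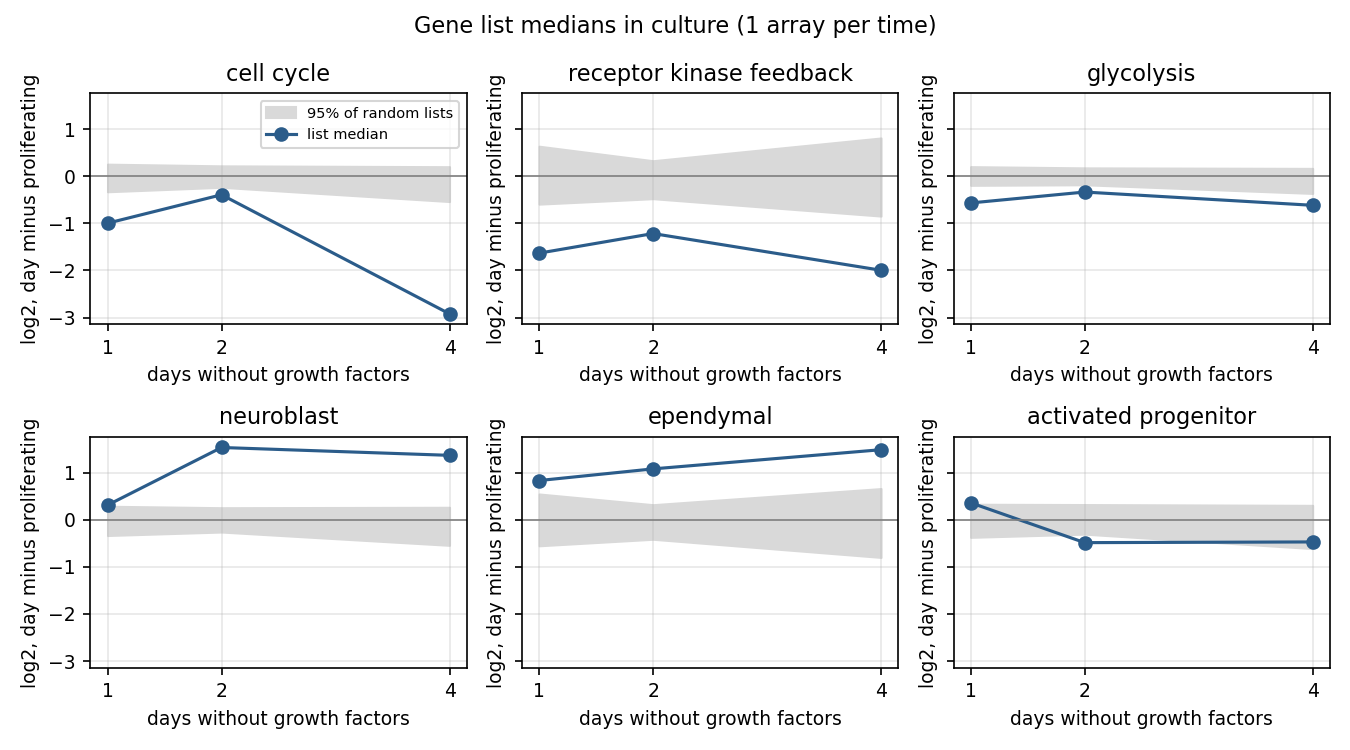
Median log2 difference from the proliferating culture on days 1, 2 and 4 (points, 1 array per day) for 6 gene lists, with the central 95% of 10000 random lists in grey. Neuroblast genes had medians of 0.32, 1.54 and 1.38 and cell cycle genes of -0.99, -0.39 and -2.92, and the day 1 sign turned under other scalings for the neuroblast and activated progenitor lists.

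The comparison of culture with the sorted lineage asked whether differentiation in the dish ran along the differences between sorted populations. Across 24172 genes the day 4 difference correlated with NB minus NSC at a Pearson correlation of 0.531 and a Spearman correlation of 0.451. With TA minus NSC the Pearson correlation was 0.170 and with astrocytes minus NSC 0.171. The 9 relations computed, 3 sorted contrasts on each of 3 days, carry no p-value because genes are not independent replicates. With NB minus NSC the Pearson correlation was 0.453 on day 1 and 0.044 on day 2, the day whose array did not share the receptor signal of the NB array. As deposited, the day 4 correlation with TA minus NSC was -0.046. Over the 9137 genes above background the day 4 correlation with NB minus NSC was 0.341.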

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

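The comparison under other scalings was chosen after the result was seen. The activated progenitor list of 17 genes moved in opposite directions between culture time points, with a median log2 difference from the proliferating culture of 0.37 on day 1 and -0.48 on day 2. Each day has 1 array, and the difference between the days was not tested. Relative to the median of all genes, day 1 stood at 0.38 with the normalization used and at -0.11 with median centring and -0.29 as deposited, so its sign depended on the scaling. Day 2 stood at -0.39, -0.21 and -0.21 in the same order. On day 2 Ccnd1 was 14.8-fold lower and Dlx1 15.1-fold higher, so members of the list moved both ways.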

How the results depend on the processing

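The settings without the NB, day 1 and day 4 arrays, with only genes above background, outside the receptor range and with day 2 alone were chosen after the data were examined. Of the 53 named gene calls, 51 to 53 kept their direction and side of the threshold in each setting that measured all of them. As deposited, the counts were 16681 for NSC minus astrocytes (2008 higher, 14673 lower; median of all genes -0.39), 16667 for TA minus NSC (15811 and 856; 0.51) and 3252 for the culture (63.7% higher), with a culture correlation of 0.653. As deposited, Egfr in TA minus NSC (0.73), Cd24a in NB minus TA (-0.48), the neuroblast list in NB minus TA (adjusted p = 0.349) and the culture correlation with TA minus NSC (-0.046) reversed. Fry gave the opposite direction for the Notch list in NSC minus astrocytes (adjusted p = 0.00043) and for glycolysis in NB minus TA (0.0242); the cause was not tested for any of these. A 2-fold floor, which leaves fewer genes by construction, gave 4542 and 3366 genes for NSC minus astrocytes and TA minus NSC. Leaving out 1 replicate gave 5523 to 9543 genes for TA minus NSC, and the culture correlation ran from 0.523 to 0.531. With each array centred on its median 59.4% of calls were higher in NSC than in astrocytes and the median of all genes was 0.18. The culture rule gave 3305 genes without background correction, 10006 without the condition on days 1 and 2, 4116 at a threshold of 1.5 and 3371 for day 2 alone. The correlation was 0.554 without the dimmest 30%, 0.044 on day 2, 0.453 on day 1, 0.451 by Spearman and 0.341 over 9137 genes above background; the cause was not tested. Outside the receptor range of -0.76 to 3.73, NB minus TA held 5827 genes (305 higher, 5522 lower), fewer by construction. With an estimated correlation 0 of the 54 list tests passed at 0.05, against 34 with camera's preset and 49 with fry. The estimates ran from -0.046 (receptor kinase feedback) to 0.192 (mature neuron). They lay above the preset 0.01 for cell cycle genes (0.034) but below it for astrocyte (-0.026) and microglia (-0.038) genes. For those 2 lists a higher correlation between genes therefore cannot account for the lost calls. With an estimated correlation camera also rests on the 3 residual degrees of freedom of the fit, which gives larger p-values for the same statistic. The lost calls are thus no measure of correlation between genes alone, and the part due to each was not tested. With the replicate number as a block, 10022 genes passed for NSC minus astrocytes, 8846 for TA minus NSC and 14069 in the F-test over 6 arrays. The list count stayed at 34. The oligodendrocyte lineage call of NB minus TA was lost and an ependymal call of TA minus NSC gained (camera adjusted p = 0.0487). Replicate deviations correlated at 0.150, -0.161 and -0.103 between groups. These correlations across genes cannot show whether same-numbered arrays shared an animal or sort. Without the NB, day 1 and day 4 arrays NSC minus astrocytes held 10968 genes, TA minus NSC 10114, and 24 lists passed over both contrasts. The oligodendrocyte lineage call was lost without the dimmest 30% in NSC minus astrocytes (adjusted p = 0.0565) and NB minus TA (0.169), and the fatty acid oxidation call of TA minus NSC without TA replicate 1 (0.0549). Without TA replicate 2 the oligodendrocyte lineage call of NB minus TA was lost (0.0512). Signal over background limits the NB array most, at 6.36 times the random control mean for the 95th percentile.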

Other observations

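The gene families here, the tests on uniform hybridisation, on multi-copy families as units, on progress of differentiation, on day 1 minus day 2, on the microglial list against receptor genes and on hypoxia genes were chosen after the results were seen; the tests on multi-copy genes, on the day 2 subset and on further blood-lineage genes were fixed before their results were seen. Of 82 ribosomal protein genes 47 rose and 0 fell by limma from niche astrocytes to activated stem cells (median log2 0.50, with the same sign in 4 scalings), and 26 rose and 1 fell from NSC to TA. Histone genes rose in 35 of 72 cases between astrocytes and NSC and fell in 5. Potassium channel genes fell from NSC to TA in 32 of 70 cases and rose in 14.

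On the NB array 25 of 30 histocompatibility genes were higher than in TA and 2 lower, with a median of 1.77 that kept its sign in 4 scalings. Collagen genes were higher in 18 of 28 cases and lower in 5. These rises stand beside the receptor genes' median rise of 1.02 on the same array.

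The NB, day 1 and day 4 arrays stood apart, with signal at receptor genes that few cells express. Uniform nonspecific hybridisation was argued against as the whole cause, because receptor genes exceeded the random controls by at least 1.38 times on these arrays and by at most 1.18 times on the other 8. Progress of differentiation cannot be told apart from chance between arrays: day 2 minus day 1 was -1.05 at the receptor median (SE over genes 0.05), but each day has 1 array. Genomic DNA or repeat sequence could contribute, but cannot be told apart from other causes: 96 tissue-restricted multi-copy genes had a median rise over the other 8 arrays that exceeded that of 39 single-copy genes by at least 1.17 (log2) on each array (permutation p up to 0.0027), but related genes are not independent. With 9 gene families as units the p was 0.0093 for NB, 0.12 for day 1 and 0.0064 for day 4, and the differentiation state of NB cells remains untested.

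The day 4 change in culture correlated with NB minus NSC, and 2 sources may contribute. A signal shared by the arrays could do so, since day 1 minus day 2, an interval run backwards in time, correlated with NB minus NSC at 0.449 across genes. A differentiation change common to dish and tissue also remained open: the day 2 change, which lacks the receptor signal, correlated with NB minus NSC at 0.183 over 2613 genes at least 2-fold apart on day 2 and above background on day 2 or in proliferation. The day 2 value over all genes, 0.044, had been seen before that test, and genes are not independent replicates.

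All 18 microglia genes were higher on the NB array than in TA. The list's median rise exceeded that of the receptor genes by 1.95 (bootstrap SE 0.22), more than a uniform shift at the receptor median would give. Receptor genes spread widely, however, and only 2 of 18 microglia genes exceeded the upper end of the receptor range, 3.73. On days 1 and 4 the microglia list had medians of -0.003 and 0.82 over the proliferating culture, below the receptor genes' 0.99 and 1.89. On those arrays a shared signal was thus no larger at microglia genes than at receptor genes. Each of these days has 1 array, and 12 of 18 members allowed no fold there. The size of the shared signal at microglia genes on the NB array is not known, so these values cannot exclude it as the cause. Microglia or other blood-lineage cells in the neuroblast sort are a candidate source: 96.7% (29 of 30) of further blood-lineage genes, none of them in the microglia list, were higher on the NB array, with a median of 2.83, and 26 of 30 were above background there. The abundant microglia genes C1qa (13.98 against 10.98 and 10.96 in TA) and Csf1r (14.27 against 11.22 and 11.39) were high on the NB array in log2 level. The labels name no gate against such cells, brain tissue holds microglia, and the share of such cells was not estimated.

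A lower hypoxia response after the medium change may go with the falls of Vegfa, Adm and Slc16a3 in culture. A list of 24 other hypoxia-induced genes had medians of -0.93 on day 1, -0.80 on day 2 and -0.81 on day 4, with 0, 0 and 1 of 10000 random lists as low. Of these genes 6 are in the glycolysis list, which had been seen to be lower, and the 18 others had medians of -0.98, -0.80 and -1.03. Ero1a (-2.46, -1.90 and -2.28) and Bhlhe40 (-1.18, -1.61 and -2.06) were lower on all 3 days, while Ndrg1 was higher (0.25, 0.21 and 0.72). The list's sign held in 4 scalings, but each day has 1 array, and oxygen was not measured in these data.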
